A study of Rattus norvegicus with 8 samples.

How the data were processed

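Per the labels, the samples were intact upper spinal cord of Sprague Dawley rats, an outbred laboratory strain. All rats had a hemisection at the ninth thoracic segment (T9) and were sampled 23 days later. Per the labels, 4 samples came from trained and 4 from untrained animals; the kind of training, its start, the sex of the animals and the segment dissected are not given in the sources used here. The titles and columns all carry the code L1, which the labels do not explain; whether it names a segment is unknown, so the position of the tissue rests on the word upper in the labels. RNA from frozen tissue was made into CEL-Seq2 libraries for the Illumina HiSeq1500, per the labels' protocols. CEL-Seq2 primes on the poly(A) tail, adds a sample barcode and a unique molecular identifier (UMI) to each molecule, amplifies linearly by in vitro transcription, and so counts 3' ends of transcripts.

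The authors deposited 1 table of whole-number counts for 32883 Ensembl rat gene IDs with 1 column per sample; its name calls them UMI counts. The submitters' processing notes list HISAT2 2.0.4, HTSeq 0.6.0 and the genome build Rnor_6.0. The annotation release, the UMI length, the strand setting and the rules for collapsing UMIs are not given in the sources used here. Each line of the table carries an Ensembl ID. The 8 column names hold the same 2 parts as the sample titles in the other order, and each matched 1 title. The deposited table does not pair IDs with symbols, and 0 of its IDs matched the gene table used here, which carries no Ensembl IDs. Genes are therefore unnamed. The 40 lists of cell-type markers and pathways fixed before the data were examined could not be matched, and the planned set tests were not run.

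Groups were taken from the labels. Trained and untrained samples were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter (minimum count 10, minimum total 15, by group), library totals were recomputed over the kept genes and scaled by TMM, and a quasi-likelihood F test on group was run with Benjamini-Hochberg adjustment at a threshold of 0.05. All 8 samples entered 1 model with no covariate. CPM values are counts scaled to a common library size, here by the TMM-scaled totals of the kept genes, and log2 CPM for components and correlations used a prior count of 2. Intervals of fold changes are 95% intervals from the quasi-likelihood standard error and are not corrected for the number of genes. Single values per library were compared by a two-sided exact permutation test over the 70 allocations of 8 samples, whose smallest possible p is 0.0286. They were also compared within same-number pairs by a two-sided exact permutation of the 16 sign flips, whose smallest possible p is 0.125; this was added after the data were examined.

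Library totals ran from 141737 to 298262. A gene with 0 counts in a library could be present at up to 10.1 to 21.2 CPM of that library's total (3 counts); such floors cover counting error only. The labels do not say that the samples came from separate animals, and p-values then measure the spread between these samples. No 2 columns were identical. Over the genes tested, the chi-square statistic per degree of freedom for the 12 sample pairs within groups ran from 2.70 to 6.60, so each pair differed by more than sampling noise. Repeat libraries of one animal could differ as much through their preparation, so this does not show that the samples are separate animals, and the 8 columns entered the fits as 8 samples because the labels list them so.

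The titles number the samples 1 to 4 in each group, without saying what the number stands for. Whether it pairs the samples was checked on log2 CPM as the correlation, across genes, of each sample's deviation from its group mean. The 4 same-number correlations were 0.34, 0.40, 0.27 and 0.51, all over the 0.1 set as the limit. The highest value between other numbers was 0.256, just under the lowest same-number value of 0.266. The mean over other numbers was -0.12, which centring on group means nearly fixes given the same-number values. The real matching had the highest mean of the 24 possible matchings, which is the smallest share they can give, and all 8 samples correlated best with their own number in the other group. In genes with a mean count of 100 or more, 7 of 8 did so, and the highest other value (0.487) passed the lowest same-number value (0.480). The numbers were therefore treated as pairing the samples, and the fit with the number as a block is given beside results that it moves. This is evidence from the counts and not from the labels.

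The alternatives set before the data were examined were DESeq2 1.42.0, DESeq2 size factors in edgeR, total counts without TMM, no filter on low counts, at least 10 counts in at least 4 samples, the replicate number as a block, leaving out each sample, leaving out the 20 most abundant genes, limma 3.58.1 voom with sample quality weights, and counts thinned to the smallest library. The genes given by ID are the 2 with the smallest p in each direction. The rule fixed beforehand ranked 12 per direction; the rest are summarised because they have no symbol.

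The fits were tested on simulated data. Negative binomial counts were drawn for the 3016 tested genes from the fitted means, library totals and dispersions of this comparison, with 200 genes changed by 1.5-, 2- or 3-fold, in 10 draws. With the fitted number effects kept in the means, the fit without the block recovered 0.149% of the 1.5-fold, 16.3% of the 2-fold and 63.5% of the 3-fold changes, and the blocked fit recovered 25.1%, 67.5% and 84.5%. These shares are of all changed genes, including those that the expression filter removed from the simulated counts (2783 to 2823 of the 3016 genes were kept). Of the changed genes that were kept, the fit without the block recovered 0.165%, 18.4% and 74.6%, and the blocked fit 27.7%, 76.1% and 99.3%. With no number effect, the fit without the block recovered 39.1% of all 2-fold and 80.9% of all 3-fold changes, and the blocked fit 34.6% and 78.9%. Wrong calls made up 0% to 5.61% of all edgeR calls. The simulated same-number correlation had a median of 0.52, above the mean of 0.38 in the data, so the simulated number effect was larger than the real one.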

Results

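The transcriptome of intact upper spinal cord after a T9 hemisection was measured in 4 trained and 4 untrained rat samples, 23 days after the injury. The question was which transcripts of this tissue differ with training. Libraries held 191502, 216603, 152764 and 141737 counts for trained samples 1 to 4 and 298262, 287908, 201445 and 179264 counts for untrained samples 1 to 4. Between 8300 and 9872 genes had at least 1 count in a library. Of 32883 gene IDs, 20338 had no count in any library, and the 3016 that passed the expression filter held 88.6% of all counts. The 18 genes with a mean count of 1000 or more held 17.7% of all counts. Because the table gives Ensembl IDs alone, genes are reported by ID or by abundance.

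Trained libraries were shallower than untrained ones. The mean total was 175652 ± 34652 counts (SD, n = 4) with training and 241720 ± 60148 counts (SD, n = 4) without, and the trained library was the smaller one at each of the 4 sample numbers. The ratio of 1.38 was not larger than the spread over unpaired samples (two-sided exact permutation test, p = 0.143, adjusted p = 0.343 over 4 library measures). Genes detected numbered 8775 ± 499 with training and 9394 ± 514 without (SD, n = 4; exact permutation p = 0.171, adjusted p = 0.343). The 10 most abundant genes took 15.3% ± 2.998 of counts with training and 12.8% ± 3.21 without (SD, n = 4; exact permutation p = 0.286, adjusted p = 0.381). The highest count in a library averaged 3760 ± 238 with training and 3893 ± 195 without (SD, n = 4; exact permutation p = 0.457). Within same-number pairs the total fell by 66068 ± 30551 counts and the genes detected fell by 619 ± 162 (SD, n = 4 pairs). The total, the genes detected and the highest count were lower, and the share of the top 10 genes higher, in the trained library of 4 of 4 pairs. Each of these gave p = 0.125 by an exact permutation of signs within pairs, the smallest that 4 pairs can give.

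Samples grouped by their number and not by training. The first principal component of log2 CPM held 35.4% of the variance; the sample number accounted for 99.8% of its spread and the training group for 0.00204%. Samples 1 and 2 of both groups lay between -13.7 and -11.9 on it, sample 3 of both groups at 5.88 and 6.12, and sample 4 of both groups at 18.5 and 19.98. The second component held 18.5% of the variance, of which the number accounted for 82.7% and the group for 1.498%. The number has 4 levels and the group 2, so by chance alone the number would take the larger share. The correlation of log2 CPM across genes averaged 0.93 (range 0.92 to 0.95) for the 4 pairs of libraries with the same number in different groups. It averaged 0.89 (0.853 to 0.934) for the 12 pairs within a group, and 0.89 (0.853 to 0.935) for the 12 pairs that shared neither. The ranges overlapped: untrained 1 correlated at 0.921 with trained 1, but at 0.935 with trained 2 and 0.934 with untrained 2. Genes are not independent replicates, so these correlations carry no p. In an edgeR quasi-likelihood fit with number and group, 381 of the 3016 genes differed among the 4 numbers at an adjusted p under 0.05.

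**Figure D1:**
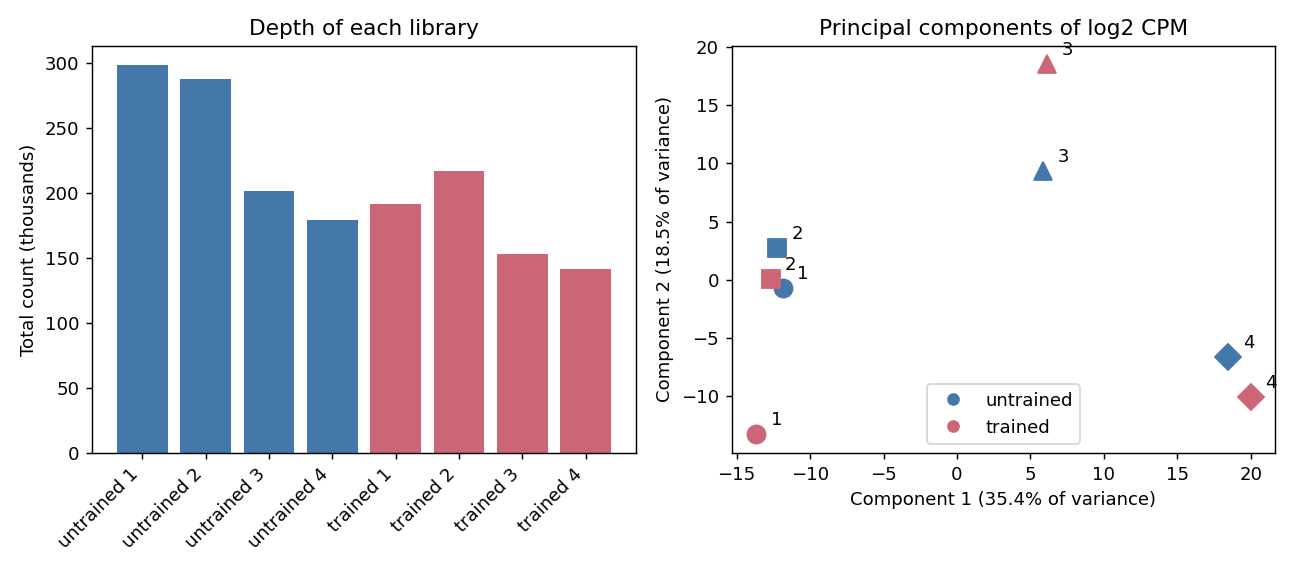
Left, total count of each library, with untrained libraries in blue and trained libraries in red. Right, the first 2 principal components of log2 CPM over 3016 genes, with 1 point per library marked by its sample number; libraries of the same number lie together along component 1 (35.4% of the variance), whereas the groups overlap.

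No gene differed between trained and untrained spinal cord past the threshold. Of the 3016 genes tested, 1476 had a higher and 1540 a lower fitted level with training, and 0 reached an adjusted p under 0.05; the lowest adjusted p was 0.647 (edgeR quasi-likelihood test, Benjamini-Hochberg). DESeq2 called 0 genes, with 60 of 12539 at an unadjusted p under 0.05 (25 of the 3015 it shared with edgeR), and limma voom with sample quality weights called 0, with 53 of 3016. At an unadjusted p under 0.05 there were 51 genes, 24 higher and 27 lower, where an even spread of p would give 151. With the sample number as a block, edgeR again called 0 genes, its lowest adjusted p was 0.108, and 154 genes, 87 higher and 67 lower, had an unadjusted p under 0.05. Blocked fits without both samples of number 1, 2, 3 or 4 called 4, 1, 0 and 2 genes, all with a higher level in trained samples, so the count of 0 with the block rests on keeping all 4 pairs or leaving out number 3. Of the 51 genes, 50 were among the 154. The estimated biological coefficient of variation was 24.2% without the block and 13.7% with it. Without the expression filter, edgeR called 6 genes, of which 1 had passed the filter. DESeq2 gave a p for 12539 of the 12545 genes tested without the filter. Its adjusted p was at least 0.999 for those of the 6 that were among them.

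**Figure D2:**
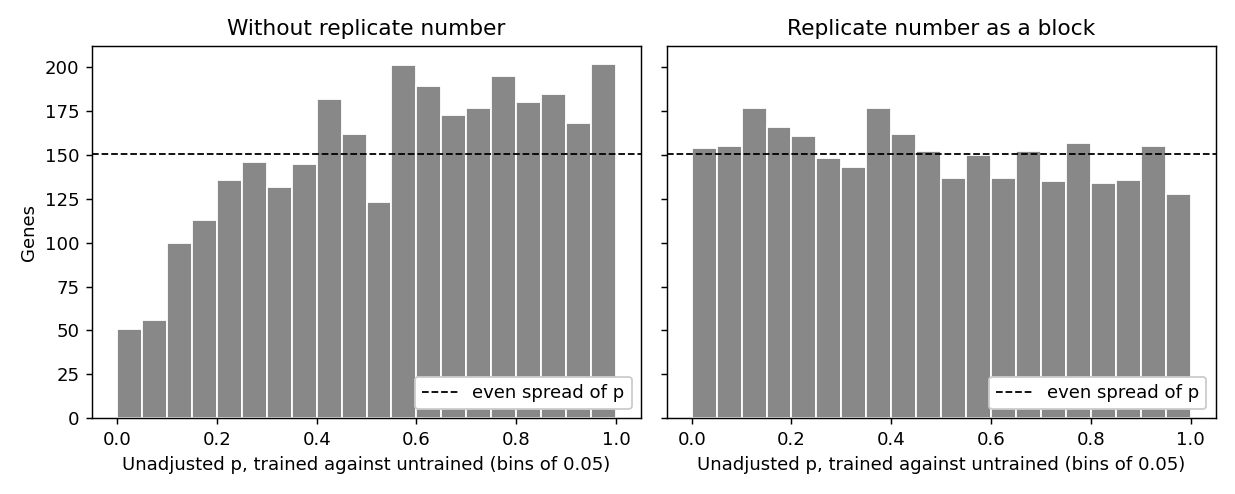
Number of genes in each 0.05-wide bin of unadjusted p for trained against untrained, without (left) and with (right) the sample number as a block; the dashed line marks an even spread (151 genes per bin). The lowest bin holds 51 genes without the block and 154 with it.

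The gene with the smallest p, ENSRNOG00000018991, was measured at 234 ± 74.9 CPM with training and 96.5 ± 15.1 CPM without (SD, n = 4), a ratio of 2.42 between the means. Its fitted log2 fold change was 1.31 (SE 0.28, 95% interval 0.72 to 1.89, adjusted p = 0.647 by edgeR). The trained value was the higher one in all 4 same-number pairs, and the counts behind it ran from 19 to 61 with training and from 17 to 26 without. With the number as a block its log2 fold change was 1.30 (SE 0.22, adjusted p = 0.108). In blocked fits without both samples of number 1 and without those of number 4 its adjusted p was 0.0173 and 0.0186, and without those of numbers 2 and 3 it was 0.731 and 0.467, so whether it is called rests on which pairs are kept. Over the 22 alternative settings its adjusted p ran from 0.0013 to 0.9999. The lowest came from edgeR with the block and no filter, the only 1 of the 22 that called it. That fit did not use each gene's own spread. ENSRNOG00000017869 was measured at 551 ± 137 CPM with training and 328 ± 69.6 CPM without (SD, n = 4; log2 fold change 0.76, SE 0.24, adjusted p = 0.999 by edgeR), with the trained value higher in 3 of 4 pairs and, in the pair of samples 3, at the same level of 389 CPM.

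Of the genes with a lower fitted level in trained samples, ENSRNOG00000004518 had the smallest p. It was measured at 43.9 ± 7.23 CPM with training and 98.3 ± 31.4 CPM without (SD, n = 4), with a log2 fold change of -1.13 (SE 0.34, adjusted p = 0.999 by edgeR). Its counts were 5 to 10 per trained library and 12 to 25 per untrained library. ENSRNOG00000001242 was measured at 83.8 ± 13.8 CPM with training and 154 ± 31.7 CPM without (SD, n = 4; log2 fold change -0.87, SE 0.27, adjusted p = 0.999 by edgeR). Both were lower in all 4 pairs, and with the number as a block both had an adjusted p of 0.770.

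**Figure D3:**
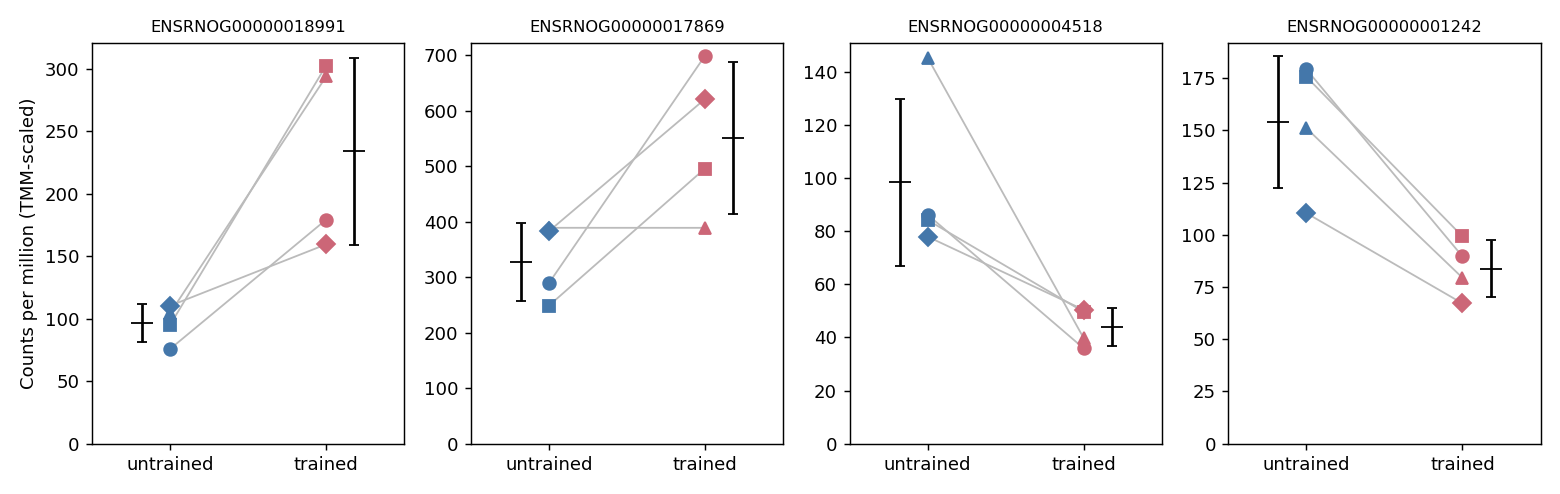
Level in CPM of the 2 genes with the smallest p in each direction, with 1 point per library, grey lines joining samples of the same number, and black bars for mean ± SD (n = 4). ENSRNOG00000018991 lies between 75.8 and 110 CPM in untrained and between 159 and 303 CPM in trained libraries; none of the 4 genes passed the threshold.

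The 12 genes with the smallest p in each direction had log2 fold changes of 0.66 to 1.31 and of -0.58 to -1.17, and none passed the threshold. In each direction, 11 of the 12 moved one way in all 4 same-number pairs. Of the 12 higher genes, 8 were also among the 12 with the smallest p in that direction with the number as a block, and of the 12 lower genes, 6. These counts come from the same samples that gave the ranking, so they follow in part from it and are no separate evidence.

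Median fold changes are given by abundance; no test of the difference between classes was run. The 1790 genes with a mean count under 30 had a median log2 fold change of -0.01, and the 251 genes with a mean count of 100 to 300 one of -0.02. The 64 genes with a mean count of 300 to 1000 had a median of 0.06, with 41 higher and 23 lower. The 18 genes with a mean count of 1000 or more had a median of 0.27, with 17 of 18 higher in trained samples, though none passed the threshold. This median was 0.16 without untrained 1, 0.16 without untrained 2, 0.17 without trained 3 and 0.40 without untrained 4. With counts corrected for a ceiling of 4 to the power 6 it was 0.12, with 15 of 18 higher. The corrected median was 0.05 without untrained 1, 0.04 without untrained 2 and 0.05 without trained 3. It was 0.22 without untrained 3, 0.21 without untrained 4 and 0.23 without trained 2. With the number as a block their median was 0.26, with 18 of 18 higher, and 9 of the 18 had an unadjusted p under 0.05 in that edgeR fit, against 1 without the block. These are the genes whose counts scaled least with library depth: across the 8 libraries the median slope of log2 count on log2 depth was 1.03 for genes with a mean count of 10 to 30 and 0.09 for the 5 genes with a mean count of 3000 or more.

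**Figure D4:**
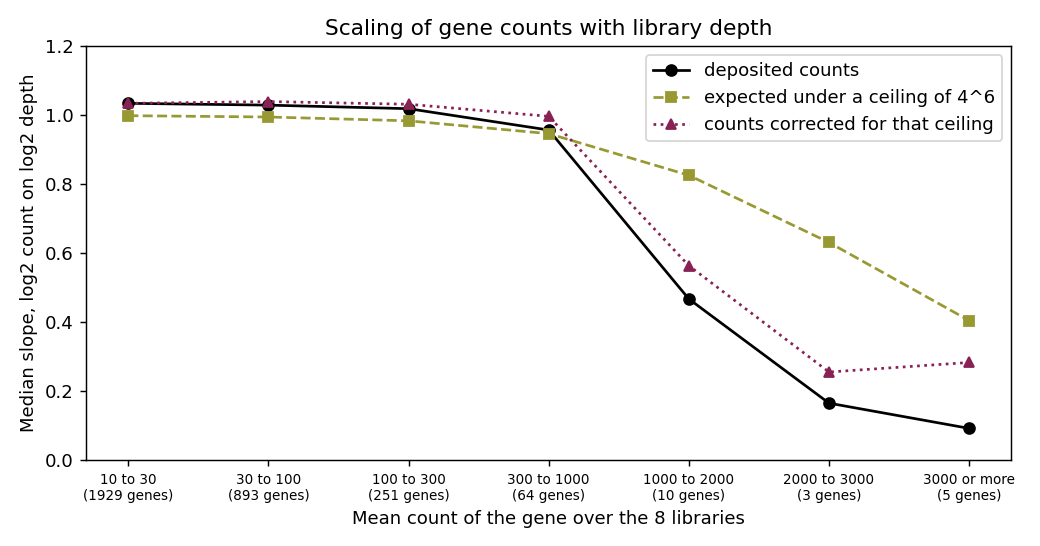
Median slope of log2 count on log2 depth over the 8 libraries, by the mean count of the gene (depth is the total over genes with a mean count under 200). Slopes of the deposited counts (black) fall from 1.03 to 0.09 as abundance rises; the green squares give the slope that a ceiling of 4 to the power 6 molecules per gene would give, and the purple triangles the slope after correcting counts for it. The 3 highest classes hold 10, 3 and 5 genes.

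The precision of fold changes varied with abundance and with the block. The median standard error of a log2 fold change was 0.30, and the 95% interval reached 1.56-fold to either side at the median gene. For 2274 of the 3016 genes (75.4%) the interval lay within a 2-fold change in both directions, and with the number as a block for 2607 genes (86.4%). Among genes with a mean count under 30 the share was 62.6%, and among those of 30 to 100 it was 92.8%. The median standard error was 0.33 for genes with a mean count under 30, 0.22 for those of 300 to 1000 and 0.27 for those of 1000 or more. With the block these were 0.28, 0.12 and 0.13. For genes whose interval reached past 2-fold, such a difference was not excluded. With the number effect simulated, the fit without the block recovered 0.149% of the 1.5-fold and 16.3% of the 2-fold changes. The blocked fit recovered 25.1% and 67.5%. With no number effect, the fit without the block recovered 6.87% and 39.1%. Changes under 1.5-fold were not simulated. The count of 0 calls therefore says little about 1.5-fold changes, and without the block little about 2-fold ones.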

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

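Among 20 sets of 4 values examined (library measures and the CPM of the 4 genes given by ID, per group), 2 held a sample far from the other 3, where chance gives about 1 in 20. The highest count in a library was 3603 in untrained sample 1, against 3954 to 4012 in the other untrained libraries. Among trained libraries the lowest such value, 3463, was also in sample 1. The level of ENSRNOG00000004518 was 145 CPM in untrained sample 3, against 77.9 to 86.1 CPM in the other untrained libraries. These were 25 counts in that library, and all 4 untrained values lay above the highest trained value of 50.4 CPM. No explanation was tested for either value.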

How the results depend on the processing

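The fits with counts corrected for a ceiling, and those combining thinning, DESeq2, the ceiling or no filter with the replicate block, and the blocked fits without both samples of one number, were chosen after the data were examined. The count of 0 genes past the threshold by edgeR, DESeq2 or limma voom held in 20 of 22 alternatives. The exceptions were edgeR with no filter on low counts, which called 6 genes (2 higher, 4 lower), and the same with the replicate block, which called 8 (3 higher, 5 lower). In 3 of the 6, 207, 67 and 47 counts came from 1 untrained library and at most 4 from any other. Without the filter edgeR gave its prior for the spread unlimited weight (prior degrees of freedom 10.5, and 11.3 with the block, with the filter), so the p-values did not use each gene's own spread. The number of genes at an unadjusted p under 0.05 (51, limma voom 53) was 49 to 75 when samples were left out in turn. It moved to 154 with the replicate block, 145 with the block and the ceiling correction, 136 with the block in thinned counts, 359 of 12545 genes with no filter, and 486 with no filter and the block. It was 60 of 12539 by DESeq2 and 42 of 12545 by DESeq2 with the block. Blocked fits without both samples of number 1, 2, 3 or 4 called 4, 1, 0 and 2 genes, all higher with training. The 4 genes given by ID kept their direction in all 22 alternatives each; ENSRNOG00000018991 was called in 1 (no filter with the block, adjusted p = 0.0013 by edgeR; range over alternatives 0.0013 to 0.9999), and the others in none. Set tests on the fixed gene lists, and their alternatives, were not run because the IDs could not be matched to symbols. Precision was lower for genes with few counts: 62.6% of those with mean counts under 30 had an interval within 2-fold, against 92.8% of those with 30 to 100.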

Other observations

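The tests of the missing small p-values, the fits without both samples of one number, the checks of unfiltered calls and of DESeq2 over the same genes and on simulated counts, and the correction for a ceiling were chosen after the data were examined. The reading of the test of the missing small p-values was also changed after its result was seen. The same holds for the tests set beforehand of depth for the abundant genes and of shared signs. It also holds for those of depth and of dominant genes for the same-number deviations, as stated with each. An abundant gene without a symbol had 684 to 1905 counts in trained and 581 to 1194 in untrained libraries, or 8896 ± 3411 and 3943 ± 2347 CPM (SD, n = 4). It was higher with training in 4 of 4 same-number pairs (log2 fold change 1.18, SE 0.37, adjusted p = 0.999 by edgeR; 1.28, SE 0.26, adjusted p = 0.266 with the block). It was called without the filter (adjusted p = 0.0482 by edgeR, and 4.65e-19 with the block) and in the blocked fits without number 1 and without number 4. Without the filter the block fit took its spread from the trend of all genes (0.593, against 2.77 with the filter), so these p-values do not reflect its own spread. It was singled out after its values were seen.

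Samples of the same number deviated together, with correlations of 0.27 to 0.51 across genes. In counts thinned to 141737 per library the lowest same-number correlation was 0.26, and the real matching was still the highest of 24. Without the 20 most abundant genes the lowest correlation was 0.27. Both met the bounds set beforehand against depth and a few dominant genes, but these were set aside after the results were seen. Thinning keeps the expected share of each gene, so it argues only against unequal totals as such. In each group samples 1 and 2 had larger totals than samples 3 and 4, so depth follows the number in part. The correlation weighs all genes alike, so leaving out 20 could hardly change it. Neither depth nor a few dominant genes is excluded. A shared day, litter, dissection level or library batch behind the number may underlie the 381 genes that differed among numbers, and these cannot be told apart because no label ties the number to any of them. No biological explanation was tested.

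Fewer genes had a small p than chance gives, 51 against 151. A candidate explanation is that a level shared by samples of one number was left out of the fit. With the number as a block edgeR gave 154, but DESeq2 over the same genes gave 25 without and 29 with the block, both far from 151. Counts simulated with the fitted number effect and no training effect gave edgeR 12 to 21 genes without the block and 124 to 152 with it (10 draws, 2784 to 2832 genes past the filter, 139 to 142 by an even spread of p), and DESeq2 8 to 14 and 24 to 26 (3 draws, 3016 genes); without a number effect they gave 117 to 143 (2761 to 2826 genes) and 102 to 120 without the block. The explanation was read as left open when the DESeq2 counts of the data were seen. This was taken back once DESeq2 with the block gave few small p-values in the simulation either way (48 to 62 without a number effect). That simulation fitted DESeq2 to 3016 genes alone, in 3 draws. In the data it was fitted to the whole table (12545 genes with a p in the blocked fit). The DESeq2 counts are therefore not like for like and do not decide the question. A number effect may account for the deficit, but the simulation did not reproduce its size. Counts with the number effect were drawn from edgeR's own blocked fit. Their near-even spread of p with the block was thus nearly fixed in advance and is no check. The simulated number effect was larger than the real one (same-number correlation 0.52 against 0.38). Without the block it gave 12 to 21 genes by edgeR and 8 to 14 by DESeq2, below the 51 and 25 of the data. In the data, the 8 splits of the samples that part all 4 numbers gave 38 to 58 genes by edgeR without the block. Splits that keep some numbers together gave 60 to 800. The deficit is therefore not particular to the split by training and went with balance over the numbers.

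The 18 most abundant genes had a median log2 fold change of 0.27, against -0.01 for the other genes, and it was 0.16 without untrained 1, 0.16 without untrained 2, 0.17 without trained 3 and 0.40 without untrained 4. A ceiling on the count of a gene may contribute, since the highest count was 97.9% of 4 to the power 6 and the most abundant gene had 3463 to 4012 counts (a ratio of 1.16) while totals differed by a ratio of 2.10; the UMI length is not given in the sources used here. Correcting for that ceiling lowered the median to 0.12 (15 of 18 higher), a fall seen in 8 of 8 fits with a sample left out (by 0.10 to 0.19) but smaller than the spread of the median itself over those fits (0.04 without untrained 2 to 0.23 without trained 2 once corrected), and left the slope on depth of the genes with a mean count of 3000 or more at 0.28. Such a ceiling would give slopes of 0.83, 0.63 and 0.40 for mean counts of 1000 to 2000, 2000 to 3000 and 3000 or more. The deposited counts gave 0.47, 0.17 and 0.09, so the ceiling alone falls short of the slopes seen. Nor did the highest count of a library rise with depth. It was 3603 in the deepest library (untrained 1, 298262 counts) and 3954 in the shallowest (trained 4, 141737 counts). In each group it was lowest in sample 1 (3603 untrained, 3463 trained). In thinned counts the median was 0.24 (17 of 18 higher), 0.25 above the other genes, which met the bound set beforehand against lower depth as the cause; that bound was set aside after the result was seen, because thinning keeps the expected share of each gene and so nearly fixes the outcome. Depth, a ceiling and training therefore cannot be told apart for these genes, since the trained libraries were also the shallower ones.

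For the count of 0 genes past the threshold by edgeR (51 at an unadjusted p under 0.05, 60 by DESeq2 and 53 by limma voom, each with 0 called), chance cannot be excluded; all 35 splits of the 8 samples into 4 and 4 gave at least as many, but a count of 0 fixes this in advance, so the splits give no evidence on chance. The highest other split gave 323 genes and set samples 1 and 2 of both groups against samples 3 and 4, the shallower ones in each group. Samples 1 and 3 of both groups against 2 and 4, and 1 and 4 against 2 and 3, gave 0 genes past the threshold. These splits had 107 and 225 genes at an unadjusted p under 0.05 by edgeR. The 323 genes thus point to a structure along that 1 split, which number and depth share. Among the 8 splits that part all 4 numbers, the real one gave 51 genes at an unadjusted p under 0.05 and the others 38 to 58, with at most 1 gene past the threshold.

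A hypothesis was that training shifted many genes slightly. The share of genes with the same sign in all 4 same-number pairs was 15.1%, where independent signs give 12.5%, and the other 7 ways to assign the signs gave 9.58% to 15.9%. The bound set beforehand against the hypothesis, a share under that of any of the 7, was therefore met. After this was seen, the bound was no longer taken as decisive, because the order turned in thinned counts (15.4% against at most 14.7%) and 8 patterns cannot give a share under 0.125. In genes with a mean count of 100 or more the share was 18.6%, with a highest other of 20.1%, and in counts corrected for a ceiling 14.6%, with a highest other of 16.1%. The mean correlation between the pairs was highest for the real signs in genes with a mean count of 100 or more (0.0978, highest other 0.0885) but not in all tested genes (0.00843, highest other 0.0371), thinned counts (0.0178, highest other 0.0329) or counts corrected for a ceiling (0.00845, highest other 0.0369). The measures differ, and the data neither show such a shift nor exclude one.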
